A study of Homo sapiens with 18 samples.

How the data were processed

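The study used OCI-Ly18, an established human diffuse large B-cell lymphoma line, made to express green fluorescent protein and grown as tumours under the skin of immunodeficient NSG mice. Per the labels' protocols, mice received tazemetostat (EPZ6438, an inhibitor of the histone methyltransferase EZH2, 150 mg/kg daily by mouth) or vehicle for 14 days from day 3 after implantation. They were then given CART19 cells, T cells with a chimeric antigen receptor, and fluorescent tumour cells were sorted from dissociated tumours 11 days after the infusion. The labels also name a UTD cell infusion, and such samples were not analysed here. Whether the drug was continued after the infusion is not stated. Total RNA was made into libraries with the NEB NEXT Ultra II kit.

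The deposited table holds whole-number read counts for 58735 Ensembl genes in 18 libraries, with no normalization, per the file headers and the values. Per the submitters' processing notes, the build was hg38 and DESeq2 was used, with no version or role given. The aligner, counter, annotation release and strand setting are not given in the sources used here. All 58735 gene IDs had the same chromosome, start and end in GENCODE release 29, whose coordinates are used below. Gene symbols were taken as the table gives them. Gene lengths were deposited beside the counts by the authors and were used only in a check of length bias. Because strand and multi-mapping settings are not stated, overlapping genes, antisense genes, histone genes, HLA genes and pseudogenes are uncertain. This holds whether or not it is said beside each value.

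The titles name 6 mice with libraries A, B and C each, 3 mice in the vehicle group (M_766, M_769 and M_770) and 3 in the tazemetostat group (M_767, M_768 and M_774). The meaning of the letters is not stated. The mouse received the treatment, so the 3 libraries of a mouse were summed and n = 3 mice per group. Libraries held 16124494 to 26336269 counts and mouse sums 55712115 to 69816184. Across pairs of libraries with different mice and the same letter, deviations from the mouse means had a mean correlation of -0.0041 across genes, and over different letters 0.0021, so the letters were not treated as pairing the samples. In chi-square tests over genes with a summed count of at least 20, the libraries of a mouse differed beyond sampling noise in 18 of 18 pairs, so none was treated as a repeat deposit.

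Counts of the mouse sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with its minimum count of 10, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05), which left 20301 genes. The genes removed held 0.06% of the counts. The biological coefficient of variation was 0.14. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD over 3 mice. Sums over T-cell or CD3 genes were scaled to all counts without these factors. Fold changes are tazemetostat against vehicle on the log2 scale. Their standard error (SE) is approximate, the size of the log2 fold change divided by the square root of F. For the 25 gene lists fixed before the data were examined, limma 3.58.1 camera compared each list with all other tested genes on log2 CPM (prior count 2, preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists). Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Single values per mouse were compared with two-sided exact permutation tests, which cannot give a p below 0.1 with 3 mice against 3. A floor of 3 counts was used where a gene had none, and it covers counting error only.

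The genes named were set by a rule: up to 12 genes per direction past the threshold with a symbol, mean log2 CPM of at least 1 and no overlap between the groups; because fewer than 10 qualified, the 10 genes with the smallest p; up to 4 members of each list with the smallest p; and 20 genes chosen for the tumour and treatment. Other list members and genes named beyond the rule were chosen after their values were seen, which is said again where they appear in the closing section. Some genes that the rule selected are not reported here.

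The steps were tested on simulated counts with the real gene means and library sizes. In that simulation of tazemetostat against vehicle over 19935 genes, 40% of 50 genes changed 1.5-fold were recovered, 82% of 50 changed 2-fold, and 100% of 50 changed 4-fold and of 50 changed 8-fold, with 12 false calls among 179. A list of 30 genes shifted by 0.4 on the log2 scale was called (adjusted p = 4.73e-19) and 0 of 24 other lists were. Simulated genes were independent of each other, which real genes are not. The genes changed by a set fold were drawn from those with a mean log2 CPM of at least 1, so recovery of scarcer genes was not measured.

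Alternatives set before the data were examined were other scaling factors, filters and thresholds, DESeq2 1.42.0, limma-voom, robust dispersion, the 18 libraries with the mouse as a random effect with and without the letter, the 18 libraries as independent, each letter alone, each mouse left out, equal depth, the T-cell marker level as a covariate, and lists without members of the other-cell and dissociation lists. Leaving out library M_768_C, a covariate for the dissociation-stress level, and the CD3 genes alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.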

Results

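Messenger RNA of sorted OCI-Ly18 lymphoma cells was counted in 18 libraries from 6 tumour-bearing mice. All mice had received CART19 cells after 14 days of vehicle (3 mice) or tazemetostat (3 mice). The mouse sums held 55712115 to 66053406 counts in the vehicle group and 59132193 to 69816184 in the tazemetostat group (n = 3 each, exact permutation p = 0.2). The comparison asked how prior inhibition of EZH2, the catalytic subunit of the repressive PRC2 complex, altered gene expression in lymphoma cells that were then exposed to CART19 cells.

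Libraries of the same mouse were the most alike. Their mean Spearman correlation across the tested genes was 0.986 ± 0.0041 (SD, 18 pairs). It was 0.982 ± 0.0048 for different mice of the same group (54 pairs) and 0.981 ± 0.0043 for mice of different groups (81 pairs). Genes are not independent replicates. Chi-square per degree of freedom between libraries of a mouse ran from 2.02 to 67.3, and from 2.02 to 4.81 once library M_768_C of the tazemetostat group was left out. Library M_768_C stood apart from the other libraries of its mouse, with a TMM factor of 0.901 and a mean correlation of 0.975 with them.

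In the tazemetostat group 4 genes were higher and 3 were lower past the threshold, of 20301 tested. IFI27, an interferon-induced gene, rose from 17 ± 1.61 to 36.9 ± 6.83 CPM (SD, n = 3 mice per group, log2 fold change 1.12, SE 0.139, edgeR adjusted p = 0.029). TNFSF9, the costimulatory ligand 4-1BBL, rose from 11.5 ± 0.758 to 21.2 ± 1.81 CPM (log2 fold change 0.88, SE 0.111, edgeR adjusted p = 0.029). FAS, a death receptor, rose from 14.1 ± 0.887 to 24.6 ± 0.539 CPM (log2 fold change 0.80, SE 0.097, edgeR adjusted p = 0.0277). GBP1P1, a pseudogene of the interferon-induced GTPase GBP1 whose reads are not told apart from those of GBP1 with certainty, rose from 2.43 ± 0.269 to 5.97 ± 0.167 CPM (log2 fold change 1.30, edgeR adjusted p = 0.0277).

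AMN, which encodes amnionless, a membrane partner of the cobalamin receptor cubilin, fell from 40.6 ± 1.83 to 20.7 ± 0.917 CPM (log2 fold change -0.97, SE 0.0894, edgeR adjusted p = 0.0107, n = 3 mice per group). CDC42BPB, a kinase that binds the GTPase CDC42, fell from 7.46 ± 0.526 to 3.20 ± 0.249 CPM (log2 fold change -1.22, edgeR adjusted p = 0.0277). The gene models of AMN (chromosome 14, 102922656 to 102933596, plus strand) and CDC42BPB (chromosome 14, 102932379 to 103057462, minus strand) overlap by 1218 bases, so their counts are uncertain where strand was not used. FAM167A (chromosome 8, 11421463 to 11475908) fell from 14.6 ± 1.37 to 6.95 ± 0.365 CPM (log2 fold change -1.07, edgeR adjusted p = 0.0277). IFI27 and GBP1P1 lie at chromosome 14, 94104836 to 94116698, and chromosome 1, 89407679 to 89426243. TNFSF9 lies at chromosome 19, 6530999 to 6535928, and FAS at chromosome 10, 88990582 to 89015785. Each of these 7 genes was separated between the groups in all 6 mice.

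**Figure D1:**
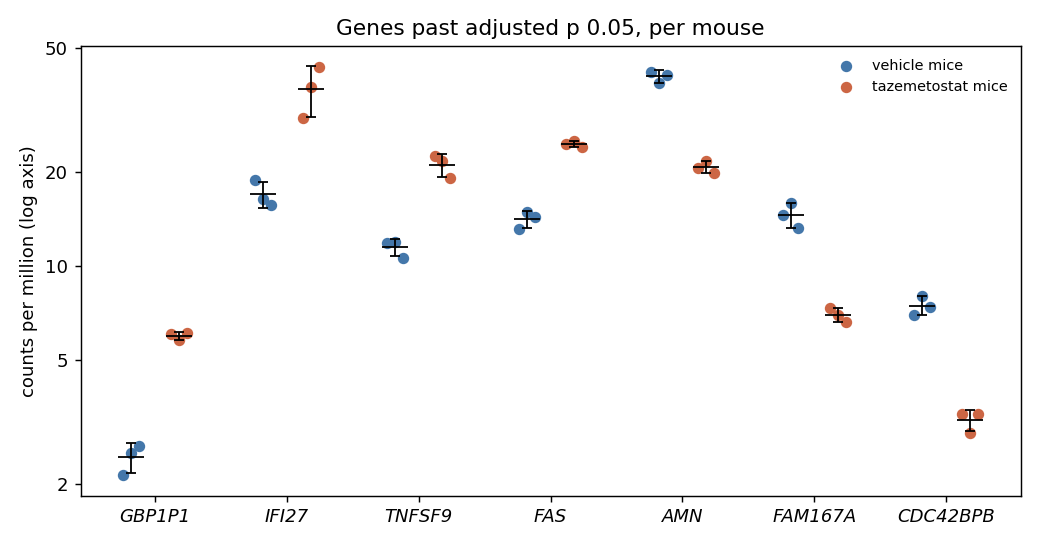
CPM of the 7 genes past adjusted p 0.05, on a log axis, with 1 point per mouse (3 vehicle, 3 tazemetostat) and bars at the mean ± SD. The groups do not overlap for any of the 7, as for FAS (14.1 against 24.6 CPM) and AMN (40.6 against 20.7 CPM).

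The next genes by p did not pass. ATF3, a stress-induced transcription factor, had an adjusted p of 0.108 with edgeR (13.4 ± 2.29 and 24.7 ± 1.23 CPM, vehicle first). TRIM22, an interferon-induced antiviral protein, followed (120 ± 2 and 194 ± 25.8 CPM, adjusted p = 0.123). The histone gene HIST1H2BG came next (7.89 ± 0.939 and 13.5 ± 0.426 CPM, adjusted p = 0.17). At an unadjusted p under 0.05 there were 1329 genes, 678 higher and 651 lower, where 1015 are expected by chance. The groups did not overlap for 12.6% of tested genes, where chance gives 10%. The count of 7 varied with the fit and the mice used, while the log2 fold changes held their direction, from -1.03 to -0.93 for AMN, 1.16 to 1.47 for GBP1P1 and 0.67 to 0.85 for FAS over 25 settings. DESeq2 called 126 genes and a fit of the 18 libraries with the mouse as a random effect 256, each including these 7. Leaving out mouse M_767, M_768, M_769 or M_774 left 1, 0, 0 and 0 genes. Leaving out mouse M_766 or M_770 gave 26 and 59. Without library M_768_C, IFI27 (log2 fold change 1.05, adjusted p = 0.0502) was lost, TRIM22 (0.71, adjusted p = 0.0486) was gained and the count remained 7.

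Interferon-stimulated genes rose as groups under tazemetostat. Of 34 type I interferon-stimulated genes tested, 33 had a positive log2 fold change (median 0.64), 31 passed adjusted over the list alone and 1, IFI27, over all genes. The list's camera adjusted p was 3.88e-26 with the preset correlation and 0.106 with an estimated correlation (fry 0.0279). The estimate was 0.241 against the preset 0.01, and a preset below the true correlation makes p too small. IFI44L was at 15.3 ± 4.28 CPM in vehicle and 42.7 ± 15.7 CPM in tazemetostat mice (log2 fold change 1.48, edgeR adjusted p = 0.183 over all genes). EPSTI1 had a log2 fold change of 0.75 and IFIT5 one of 0.66, both with an adjusted p of 0.0015 over the list alone. Of 29 interferon-gamma response genes, 28 were positive (median 0.66), 22 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 4.5e-23; adjusted p = 0.106 with an estimated correlation; fry 0.0279). Among them were IRF1, a transcription factor induced by interferon-gamma (210 ± 8.42 and 293 ± 1.45 CPM), the inflammatory caspase CASP1 (7.77 ± 0.15 and 12.3 ± 0.419 CPM) and APOL2 (66.2 ± 6.45 and 101 ± 7.81 CPM), each with an adjusted p of 0.0011 over the list alone. With the level of the dissociation-stress genes, which moved with the groups, as a covariate the interferon-gamma median was 0.36 and the type I median 0.72.

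The mean log2 CPM of the type I list was 4.29 ± 0.0599 in vehicle and 4.92 ± 0.196 in tazemetostat mice, and that of the interferon-gamma list 4.83 ± 0.309 and 5.48 ± 0.0433 (n = 3 each, exact permutation p = 0.1 for both, the smallest possible). Counts of interferon genes themselves were few. IFNG had 0, 0 and 0 counts in the vehicle mice and 1, 4 and 1 in tazemetostat mice M_767, M_768 and M_774. IFNB1 had 1, 1 and 2 in M_766, M_769 and M_770, and 1, 7 and 5 in the same tazemetostat mice. IFNL1 had 1, 0 and 0, and 0, 4 and 0. These counts are too few to compare the groups.

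**Figure D2:**
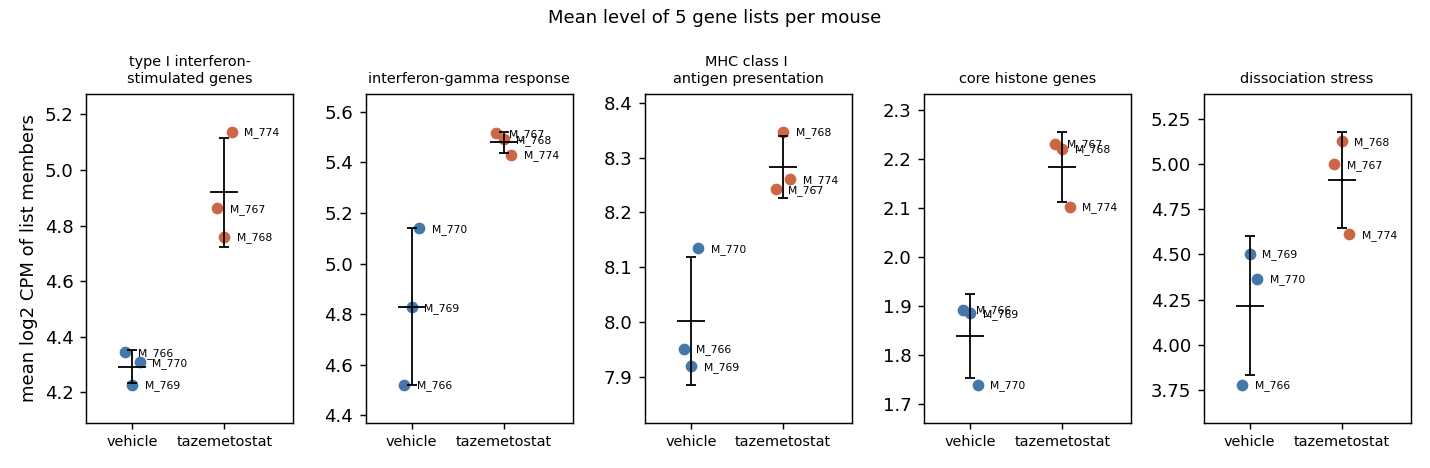
Mean log2 CPM over the members of 5 gene lists, with 1 point per mouse labelled by its number and bars at the mean ± SD of 3 mice; each panel has its own axis, which does not start at 0. The tazemetostat mice lie above the vehicle mice in all 5 panels, as for the type I interferon list (4.92 against 4.29) and the dissociation-stress list (4.91 against 4.22).

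MHC class I antigen presentation genes also rose as a group, with 20 of 21 positive (median 0.29), 9 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 1.41e-10). The call was lost with an estimated correlation (adjusted p = 0.213) and with fry (adjusted p = 0.07). The peptide transporter subunits TAP1 (512 ± 119 and 787 ± 56.3 CPM) and TAP2 (125 ± 20.1 and 178 ± 11.8 CPM) and the immunoproteasome subunit PSMB9 (182 ± 18 and 266 ± 37.2 CPM) each had an adjusted p of 0.0152 over the list alone. The gene model of TAP1 lies within that of PSMB9 on the opposite strand, so their counts are uncertain where strand was not used. The light chain B2M was at 1257 ± 102 and 1630 ± 140 CPM (adjusted p = 0.0206 over the list alone). HLA-E had a log2 fold change of 0.32 (adjusted p = 0.0206 over the list alone). MHC class II genes had 13 of 17 positive (median 0.08) and 0 passing over the list alone. The list was called with camera (adjusted p = 0.04), but not with an estimated correlation (adjusted p = 0.407) or without library M_768_C (adjusted p = 0.0914), and it lost its call in 13 of 21 other settings. The class II transactivator CIITA was at 321 ± 42.0 and 331 ± 50.1 CPM and HLA-DRA at 1840 ± 66.4 and 1948 ± 96.6 CPM, with edgeR adjusted p of 0.978 and 0.933. CTSS, a protease of the class II pathway, had a log2 fold change of 0.28, IFI30 of 0.87 at under 1 CPM, HLA-DQB1 of 0.21 and HLA-DOB of 0.24, and none of these passed.

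Inhibitory ligands rose as a group, with 9 of 10 tested genes positive (median 0.25), 5 passing adjusted over the list alone and 0 over all genes (camera adjusted p = 3.27e-05, fry 0.0279; adjusted p = 0.106 with an estimated correlation). The median was 0.04 without a low-count filter (camera adjusted p = 0.0144) and 0.13 without mouse M_766 (camera adjusted p = 0.00384). The list holds 20 genes. It shares 2 genes, CD274 among them, with the interferon-gamma list and HLA-E with the MHC class I list. These shared genes all passed over the list alone, so its rise is not independent of those lists. CD274, which encodes the checkpoint ligand PD-L1, was at 2.33 ± 0.252 CPM in vehicle and 4.23 ± 0.0556 CPM in tazemetostat mice (log2 fold change 0.85, edgeR adjusted p = 0.219 over all genes, 0.0029 over the list alone). TNFRSF14, the receptor HVEM, was at 26.2 ± 5.57 and 41.1 ± 1.84 CPM and LGALS9, galectin-9, at 26 ± 6.23 and 39.5 ± 5.25 CPM, with adjusted p of 0.00342 and 0.0108 over the list alone. The death receptor and apoptosis list had 17 of 28 genes positive (median 0.12). FAS alone passed over the list and over all genes (camera adjusted p = 0.00863; adjusted p = 0.213 with an estimated correlation, and 0.066 without mouse M_766). Its other named members did not pass: CASP10 at 0.50 and TNFRSF10B, a receptor for TRAIL, at 0.19 on the log2 scale, and the BH3-only gene HRK at -0.26.

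Core histone genes rose as a group, with 17 of 19 positive (median 0.35) and 5 passing adjusted over the list alone (camera adjusted p = 2.5e-10, fry 0.0279; adjusted p = 0.106 with an estimated correlation). The linker histone gene HIST1H1C was at 35.4 ± 3.15 and 51.5 ± 3.84 CPM and HIST1H2AE at 3.01 ± 0.338 and 5.25 ± 0.273 CPM, both with an adjusted p of 0.00348 over the list alone. HIST1H2BJ (log2 fold change 0.73) and HIST1H3H (0.54) also passed over the list alone. The list holds linker histone genes beside core ones. All are reported as uncertain, because many histone genes have near-identical copies.

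Dissociation-stress genes, which are induced while tissue is made into single cells and by stress in general, moved with the treatment group. Of 24 genes 22 were positive (median 0.71), 12 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 8.32e-11; adjusted p = 0.237 with an estimated correlation; fry 0.143). Without mouse M_766 the median was 0.44. DUSP1 was at 49.5 ± 16.6 and 96.2 ± 12.1 CPM, ZFP36 at 26.9 ± 3.92 and 39.2 ± 2.38 CPM and IER3 at 3.62 ± 0.916 and 7.85 ± 2.25 CPM, each with an adjusted p of 0.00563 over the list alone. The list's mean log2 CPM was 4.22 ± 0.385 in vehicle and 4.91 ± 0.267 in tazemetostat mice (n = 3 each, exact permutation p = 0.1). With that level as a covariate, 5 lists were called: type I interferon, interferon-gamma, MHC class I, inhibitory ligands and core histones.

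NF-kB targets, a list with 21 of 24 genes positive (median 0.24), were called with camera (adjusted p = 0.000218) but not with an estimated correlation (adjusted p = 0.407). The call was also lost without mouse M_766 (median 0.11, adjusted p = 0.0728) and without mouse M_768 (median 0.10, adjusted p = 0.0703). Their median was -0.21 with the dissociation-stress level as a covariate. IER3 and ICAM1 (65.4 ± 3.35 and 84.8 ± 4.66 CPM) passed over the list alone at 0.0174 each, whereas NFKBIE (log2 fold change 0.23) and TNF (1.09) did not. Hypoxia and glycolysis genes had 25 of 30 positive (median 0.18) and 0 passing over the list alone (camera adjusted p = 6.4e-06; adjusted p = 0.407 with an estimated correlation). Without mouse M_768 the median was 0.08 and the list was not called (adjusted p = 0.0612). ADM was at 29.8 ± 11.3 and 65.5 ± 26.1 CPM, DDIT4 at 105 ± 5.72 and 147 ± 23.6 CPM. P4HA1 was at 0.41 and VEGFA at 0.39 on the log2 scale. Fibroblast and endothelial markers had 8 of 9 positive (median 0.30) and 0 passing over the list alone (camera adjusted p = 0.00501, fry 0.0495; adjusted p = 0.158 with an estimated correlation). Without a low-count filter the median was 0.05 and the list was not called (adjusted p = 0.271). Stromal cells of the host would give mouse reads, which were not examined here. These markers were scarce, with PDGFRB at 0.247 ± 0.113 and 0.618 ± 0.178 CPM, CLDN5 at 0.148 ± 0.0633 and 0.228 ± 0.0540 CPM, TAGLN at 5.25 ± 0.882 and 6.04 ± 0.285 CPM and FN1 at 8.73 ± 1.28 and 10.8 ± 0.524 CPM.

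**Figure D3:**
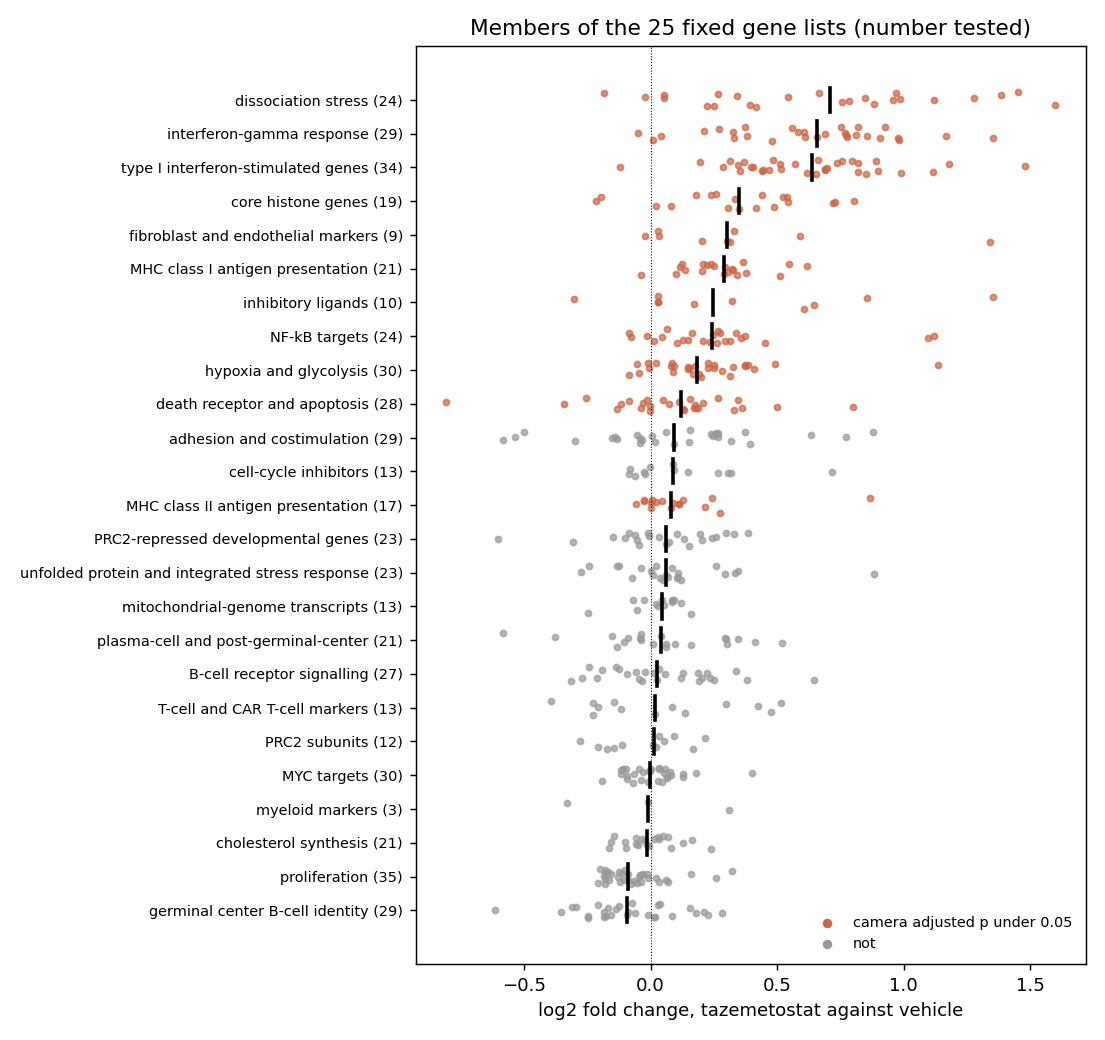
Log2 fold change, tazemetostat against vehicle, of each tested member of the 25 fixed lists, 1 point per gene, with a bar at the list's median; orange lists had a camera adjusted p under 0.05 with the preset correlation. The medians of the dissociation-stress (0.71), interferon-gamma (0.66) and type I interferon (0.64) lists lie farthest to the right.

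The messenger RNA of the drug target did not pass, nor did the PRC2 list in tests for a shift in 1 direction. The activity of EZH2 was not measured. EZH2 was at 207 ± 9.02 CPM in vehicle and 208 ± 8.40 CPM in tazemetostat mice (log2 fold change 0.01, SE 0.0853, edgeR adjusted p = 0.992). Of 12 PRC2 subunits 7 were positive (median 0.01, while camera's direction was down, adjusted p = 0.807). Without overlap between the groups 2 were higher and 3 lower, and 0 passed over the list alone. Fry without regard to direction gave this list an unadjusted p of 0.00021, so changes both ways are not excluded. EED was at 0.22, EZH1 at -0.21, MTF2 at 0.17 and PHF19 at -0.17 on the log2 scale. Of 60 PRC2-repressed developmental genes 23 were measured well enough to test. Of these, 13 were positive (median 0.06) and 0 passed over the list alone (camera adjusted p = 0.114). Its members with the smallest p were MEIS2 (9.33 ± 0.717 and 11.5 ± 0.861 CPM), PAX6 (1.94 ± 0.171 and 2.43 ± 0.305 CPM), HOXA10 (1.07 ± 0.412 and 1.41 ± 0.243 CPM) and WNT10B (0.205 ± 0.0604 and 0.134 ± 0.0501 CPM).

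B-cell lists did not pass in the main comparison. MS4A1, which encodes CD20, was at 314 ± 71.0 CPM in vehicle and 382 ± 7.61 CPM in tazemetostat mice, CD22 at 239 ± 20.6 and 214 ± 38.0 CPM and CD79B at 1120 ± 281 and 986 ± 123 CPM. The germinal center list had 19 of 29 genes negative (median -0.09, camera adjusted p = 0.114; 0.0183 down in the fit with the mouse as a random effect). BCL6, a transcriptional repressor that maintains the germinal center state, was at 101 ± 20.8 and 88.6 ± 6.36 CPM. S1PR2 was at -0.36, MME at -0.31 and CD24 at -0.25 on the log2 scale. B-cell receptor signalling genes had 15 of 27 positive (median 0.02, camera adjusted p = 0.224). They were called up without mouse M_770 (adjusted p = 0.0231) and with the T-cell marker level as a covariate (adjusted p = 0.0086). RASGRP3 (0.65) was the member that passed over the list alone, and BLK (-0.31), BCL10 (0.25) and DAPP1 (0.23) did not. Plasma-cell genes had 12 of 21 positive (median 0.04, camera adjusted p = 0.224). S1PR1 (0.52) passed over the list alone. PRDM1 (4.49 ± 0.438 and 5.98 ± 0.835 CPM), IRF4 (101 ± 16.7 and 108 ± 12 CPM), XBP1 (0.35) and DERL3 (-0.58) did not.

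Adhesion and costimulation genes had 18 of 29 positive (median 0.09, camera adjusted p = 0.0503), and the list was called up in 10 of 21 other settings, among them upper-quartile factors (adjusted p = 0.0399). TNFSF9, ICAM1 and TNFSF4, the ligand OX40L (8.16 ± 0.570 and 12.7 ± 2.28 CPM), passed over the list alone. CD58, the ligand of CD2, was at 5.40 ± 0.694 and 4.92 ± 0.338 CPM and SLAMF6 at -0.30 on the log2 scale. Cell-cycle inhibitors had 7 of 13 positive (median 0.09, camera adjusted p = 0.0532). The median was 0.01 without library M_768_C and ran from -0.05 to 0.20 with each mouse left out. CDKN1A, which encodes p21, was at 44.7 ± 12 and 73.6 ± 6.28 CPM (adjusted p = 0.0239 over the list alone). BTG2 (0.27), BTG1 (0.32) and RB1 (0.31) did not pass over this list. Proliferation genes had 28 of 35 negative (median -0.09, camera adjusted p = 0.0818). The list was called down in 6 of 21 other settings, among them upper-quartile factors (adjusted p = 0.0399) and the mouse as a random effect (adjusted p = 0.00506). MCM7 was at -0.18, E2F1 at -0.21, CCNE2 at 0.32 and RRM2 at 0.26 on the log2 scale. MYC was at 1161 ± 53.7 and 1161 ± 44.3 CPM (edgeR adjusted p = 1). Its targets had 14 of 30 positive (median -0.0014, while camera's direction was up, adjusted p = 0.807). HSPE1 was at 0.40, HSPD1 at 0.18, CAD at -0.19 and NOP56 at -0.11 on the log2 scale. The gene model of HSPE1 lies within that of HSPD1 on the opposite strand, so both are uncertain where strand was not used.

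The unfolded protein and integrated stress list had 16 of 23 positive (median 0.06, camera adjusted p = 0.0954), with ATF3 passing over the list alone and DNAJB9 (0.34) and EDEM1 (-0.28) not. Cholesterol synthesis genes had 12 of 21 negative (median -0.01, while camera's direction was up, adjusted p = 0.893). STARD4 was at 0.24, SREBF2 at -0.16, SC5D at 0.16 and HMGCS1 at 0.13 on the log2 scale. Mitochondrial-genome transcripts had 9 of 13 positive (median 0.04, camera adjusted p = 0.595). MT-ND6 was at -0.25, MT-ATP6 at 0.12, MT-ND2 at 0.09 and MT-ND4 at 0.09 on the log2 scale. Their share of counts was 4.36 ± 0.166% in vehicle and 4.54 ± 0.248% in tazemetostat mice (n = 3 each, exact permutation p = 0.3).

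Markers of other human cells were examined because the sorted fraction could hold CAR T cells. The T-cell list took 444 ± 29.2 CPM in vehicle and 409 ± 13.5 in tazemetostat mice (SD, n = 3 each, exact permutation p = 0.2, smallest possible 0.1). In this paragraph the sums and the values of TRBC2, TRAC and CD3 genes were scaled without the TMM factors, unlike those of other single genes. IL7R (223 ± 41.4 and 190 ± 4.13 CPM), ZAP70 (37.1 ± 2.05 and 32.1 ± 1.81 CPM), CD247 (36.6 ± 5.82 and 49.2 ± 3.95 CPM) and LCK (12.5 ± 1.90 and 9.48 ± 0.587 CPM) were measured in every mouse. CD3E had 1 to 9 counts per mouse, and CD3D and CD3G had 0 counts in every library, which allows up to 0.114 to 0.186 CPM per library (3 counts). The 3 CD3 genes together took 0.0922 ± 0.0613 CPM in vehicle and 0.0569 ± 0.0460 in tazemetostat mice (n = 3 each, exact permutation p = 0.6). The T-cell receptor genes TRBC2 (95.1 to 135 CPM) and TRAC (9.28 to 13.3 CPM) had counts in every mouse. The 10 most T-cell-restricted genes hold IL7R, TRBC2 and the CD3 genes. They took 351 ± 30.1 CPM in vehicle and 311 ± 10.3 in tazemetostat mice (n = 3 each, exact permutation p = 0.1, the smallest possible). The sum of the T-cell list thus rests on genes such as IL7R and TRBC2, with almost no CD3 transcripts beside them. It does not measure T cells in the sorted fraction, nor does the list's level adjust for them as a covariate. The T-cell list had 7 of 13 tested genes positive (median 0.02, while camera's direction was down, adjusted p = 0.893). Of 20 myeloid markers 3 could be tested (median -0.01, camera adjusted p = 0.918). CD14 was at 0.768 ± 0.0886 and 0.615 ± 0.205 CPM, CSF1R at 0.327 ± 0.134 and 0.4 ± 0.0567 CPM and APOE at 1.70 ± 0.264 and 1.69 ± 0.294 CPM.

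Of the 25 lists, 11 were called up and 0 down with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.106) and 5 with fry. The 5 were type I interferon, interferon-gamma, inhibitory ligands, core histones, and fibroblast and endothelial markers. Without library M_768_C, 10 were called, and MHC class II was the list lost. Among the 11, the estimated correlation was 0.575 for hypoxia, 0.425 for NF-kB, 0.394 for dissociation stress and 0.309 for MHC class I. It was 0.269 for interferon-gamma, 0.241 for type I interferon, 0.157 for MHC class II, 0.0399 for histones and 0.0222 for apoptosis. For inhibitory ligands (-0.023) and fibroblast and endothelial markers (-0.0451) it lay below the preset 0.01.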

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

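The tests of library M_768_C below were set after the library was seen to stand apart, and before their own results were seen. Among 22 groups of 9 libraries, each a measure in 1 treatment group, 5 had a library far from the other 8, where chance gives about 1 in 20. Library M_768_C accounted for 4 of the 5.

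Library M_768_C, the C library of tazemetostat mouse M_768, stood apart from the other 8 tazemetostat libraries. It had a TMM factor of 0.901 (next lowest of these 0.999) and a mean Spearman correlation with libraries of other mice of 0.972 (next 0.982). It had 7.94% of its counts in its 10 largest genes (next 7.4%) and 95.2% in protein-coding genes (next 95.4%). Over all 18 libraries it was lowest in the first 2 measures, where the next were 0.978 and 0.978, but not extreme in the others, with M_766_C of the vehicle group at 8.02% and 94.9%. For human cells of another type, the highest median log2 ratio against M_768_A and M_768_B over the T-cell, myeloid, and fibroblast and endothelial lists was 0.114. This cannot decide the question, since host cells would give mouse reads and the T-cell list does not measure T cells. The CD3 genes had 2 counts in M_768_C, 3 in M_768_A and 2 in M_768_B. Fewer distinct RNA molecules remain a candidate explanation. At equal depth M_768_C held 24056 genes with a count against at least 24729 in the other libraries. Its log2 ratios over highly expressed genes had an SD of 0.427 against at most 0.103 in libraries of other mice. A length-dependent loss cannot be told apart: gene length correlated with the log2 ratio at -0.207 across genes (genes are not independent replicates), beyond the 0.101 of other mice but short of the size set in advance. A biological difference between the portions of the tumour, if the letters stand for portions, was not tested. By chi-square per degree of freedom, M_768_C lay nearer to the libraries of vehicle mouse M_766 (29.7, 30.9 and 32.8) than to M_768_A (67.3) and M_768_B (49.4). All of these lie far above the 2.02 to 4.81 between libraries of a mouse without M_768_C. Fewer distinct RNA molecules would not alone account for M_768_C lying nearer to M_766, and the reason was not tested.

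Library M_770_A of the vehicle group had 0.347 CPM summed over CD3D, CD3E and CD3G (7 counts), against 0.11 in the next library of its group.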

How the results depend on the processing

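The settings without library M_768_C, with the dissociation-stress level as a covariate and with the CD3 genes alone were chosen after the data were seen. The 7 genes kept their direction in all 25 other settings each, and FAS, for one, kept its call in 17. Their levels did not overlap between the groups, so dropping a mouse or changing the scaling could hardly reverse a direction. The count of 7 genes (4 higher, 3 lower) became 126 (88, 38) with DESeq2, 252 (163, 89) without a low-count filter, where the fit assumed 1 common spread, 256 (170, 86) for 18 libraries with the mouse as a random effect, 1198 (666, 532) for 18 libraries as independent, which ignores the mouse, and 182 (99, 83) with the T-cell marker level as a covariate. With the library letter as a replicate block it was 224 (154, 70) against 256, and the letters share only a name. Libraries A alone gave 0 (0, 0) and C alone 0 (0, 0) with edgeR (1361 and 687 genes at unadjusted p under 0.05); B alone gave 6 (5, 1), 4 of them among the 7. Fewer counts entered those fits. limma-voom gave 5 (2, 3), all among the 7, a 2-fold minimum gave 4 (2, 2) by construction, and the dissociation-stress covariate gave 7 (6, 1), of which IFI27 was among the 7, while the other 6 kept log2 fold changes such as -0.95 for AMN, -1.27 for CDC42BPB and 0.67 for FAS. Leaving out each mouse gave 0 to 59 genes, 0 to 38 higher and 0 to 21 lower; the edgeR counts of 0 without mice M_768, M_769 and M_774 stood beside 1067, 1012 and 943 genes at unadjusted p under 0.05, and mouse M_770 gave the 59. Other causes were not tested. The 11 called lists became 5 with the stress covariate, 0 with an estimated correlation and 5 with fry. They became 16 (14 up, 2 down) with the mouse as a random effect and 14 (12 up, 2 down) for independent libraries, and leaving out each mouse gave 8 to 13. The germinal center and proliferation lists were called down with the random effect (adjusted p = 0.0183 and 0.00506), for independent libraries (0.0291 and 0.0108) and for B alone (0.0454 and 0.00861). Proliferation was also called down on the mouse sums with upper-quartile factors (0.0399), with at least 50 counts in 3 mice (0.0326) and without mouse M_769 (0.0274). Among lists not called in the main comparison, adhesion and costimulation was called in 10 settings, cell-cycle inhibitors in 4 (median -0.12 with the T-cell marker covariate), the unfolded protein list in 3 and B-cell receptor signalling in 2. The type I and interferon-gamma lists were called in 20 of 21 settings each, all but the estimated correlation, with medians from 0.49 to 0.72 and from 0.36 to 0.79. MHC class II lost its call in 13 of 21 settings, among them without mouse M_766, M_767, M_768 or M_769. The dissociation-stress median ran from 0.44 to 0.91 with each mouse left out. The NF-kB median reversed to -0.21 with the stress covariate (adjusted p = 0.437). The T-cell list's difference of -34.6 CPM was -39.5 for the 10 most T-cell-restricted genes and -0.0353 for the CD3 genes, which hold few counts. The list's level, also used as a covariate, rests mainly on genes other than CD3 and does not measure T cells. Same-mouse similarity was 0.992 over genes with at least 100 counts in every library. RLE and upper-quartile factors moved the median of all genes to -0.0057 and -0.042. Thinned to equal totals, the mice gave the same 7 genes.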

Other observations

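The genes in the first paragraph were chosen after their values were seen, as were the tests on CD3 genes and on the interferon-gamma list with the stress covariate. DESeq2 and the fit with the mouse as a random effect, which called 126 and 256 genes, shared 108, of which 79 were higher and 29 lower under tazemetostat; 27 of them belong to the 62 tested genes of the interferon lists, all higher. Others on no fixed list included the antiviral genes IFITM1 (log2 fold change 1.06, DESeq2 adjusted p = 8.88e-05), APOBEC3G (0.58, 0.000256) and SAMD9L (0.76, 0.00849), the partner proteins PARP9 (0.70) and DTX3L (0.63), and the nucleic acid sensor TLR7 (1.07, 0.0166). Histone genes outside the list, HIST2H2BE (0.51) and HIST2H2BF (0.75), were higher, with near-identical copies that leave them uncertain. Lower genes included IL4R, the interleukin-4 receptor (-0.45, DESeq2 adjusted p = 0.0165), the cyclin CCND3 (-0.40, 0.0192), CPNE5 (-0.85, 0.000602) and WNK2 (-0.72, 0.000238). With edgeR on mouse sums none of these named genes passed, the smallest adjusted p being 0.18. DESeq2 and the random-effect fit used the same counts, so their overlap is not independent support. The random-effect fit also applied 1 correlation between libraries of a mouse, 0.354, to all genes.

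Members of the type I list that the interferon-gamma list does not hold had a median log2 fold change of 0.62 (33 genes), and members of the interferon-gamma list alone 0.63 (28 genes). FAM167A, which fell, and BLK, which did not pass (log2 fold change -0.31), are neighbours on chromosome 8 on opposite strands, 10985 bases apart.

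The interferon lists rose under tazemetostat together with the dissociation-stress list. T cells carried through the sort are argued against by the low level of the CD3 genes in both groups. Their sum was 0.0922 ± 0.0613 CPM in vehicle and 0.0569 ± 0.0460 CPM in tazemetostat mice. The difference of -0.0353, with overlapping ranges, rests on few counts and decides nothing by itself. Library M_768_C alone is argued against too, since without it the type I median was 0.61 and the camera adjusted p 1.8e-23 with the preset correlation, though with an estimated correlation the adjusted p was 0.137 without the library and 0.106 with it. With the dissociation-stress level as a covariate the type I median was 0.715 (lower quartile of members 0.444) against 0.637 without it. This fit cannot decide whether a handling-stress difference caused the rise, since the stress level did not overlap between the groups. That level ran from 3.78 to 4.50 in vehicle and from 4.61 to 5.12 in tazemetostat mice. In each group the mouse with the lowest stress level (M_766 and M_774) had the highest type I level (4.34 and 5.14). For the interferon-gamma list, tested after its value was seen, the median was 0.364 (quartiles 0.102 and 0.537) against 0.657. There too a handling-stress difference cannot be told apart. An effect of tazemetostat on the tumour cells, on the CART19 cells or on their contact may underlie the rise and stays open, as a hypothesis.

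AMN and CDC42BPB fell together. A copy number difference of the whole region is argued against by the other 35 tested genes within 1 Mb, whose median log2 fold change was -0.0046 (quartiles -0.137 and 0.0937). A narrower one was not tested, and 4 of these genes lay below -0.25, among them TRAF3 (-0.27), the nearest tested gene upstream of AMN. TRAF3 was named after its value was seen. Reads shared between the gene models remain a candidate explanation for CDC42BPB, since the spans overlap by 1218 bases and the strand setting is not stated. A joint change of both genes under the drug stays open.

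The 6 mice can be split 10 ways, too few for a share under 0.05. As many as 7 genes were called in 1 split, the real one, and the highest other gave 2. As many as 11 lists were called in 2 splits, the real one and that of mice M_766, M_767 and M_769 against the rest, which gave 12. The median of the type I list was 0.637 in the real split and at most 0.354 in size in the others. Its camera adjusted p with the preset correlation ran from 2.28e-08 to 0.978 in the others. Of these, only 0.232, 0.286 and 0.978 lay above 0.05, and every other split called at least 1 list. Calls with the preset correlation were therefore not particular to the real split. Each other split sets 2 mice of a group with 1 of the other group, so it keeps part of the group difference. The split of mice M_766, M_768 and M_774 against the rest gave 2901 genes at an unadjusted p under 0.05, against 1329 in the real one, and the cause was not tested.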
